A study of Nicotiana tabacum with 6 samples.

How the data were processed

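Total RNA from 3 control and 3 aluminium-treated samples of suspension-cultured tobacco cells was labelled with Cy3 and hybridised to single-colour Agilent arrays, 1 sample per array. Per the labels' protocols, cells in log phase were washed and kept for 18 h at 10 mg fresh weight per mL in calcium chloride (3 mM), sucrose (3%) and MES buffer (20 mM, pH 5.0) with 0 or 100 µM aluminium chloride, on a shaker at 100 rpm and 25 °C. The labelling started from 200 ng of total RNA, made into cDNA and then Cy3-labelled cRNA.

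Per the file headers, the authors' scanner files were made with Agilent Feature Extraction 11.5.1.1, which the submitters' processing notes also name without a version. The intensity used here is the processed signal deposited in these files, whose headers give statistics of background subtraction and spatial detrending within the array. It stays above 0 where the background-subtracted signal is negative, and its medians differ between arrays, so it was not scaled between them. The raw spot and background medians, also deposited as intensity, were used for an alternative. The background and outlier flags are those the authors' extraction gave. The series' value table was deposited as log2 values whose scale, centring and direction are not stated with it. Set against the array files, its columns equalled log2 of the processed signal minus the array's 75th percentile, centred on each probe's median over the 6 arrays, with a median difference of at most 0.00122 per array. Its column medians were -0.016, 0.0042 and -0.012 for control replicates 1 to 3 and 0.054, -0.026 and 0.0010 for aluminium replicates 1 to 3.

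The array had 45220 spots, of which 1417 were control spots and were left out. Spots flagged as outliers were left out too, at most 16 on an array. The log2 processed signal was averaged over the spots of a probe, and each array's 75th percentile over the 43759 probes was subtracted. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which left 28861. Log2 levels were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, aluminium minus control, without a block. Benjamini-Hochberg adjusted p-values under 0.05 were called, and a size of 2-fold was used for a second count. Folds are the antilog of the log2 difference. The single value compared outside limma, the share of signal in the 1000 brightest probes, was tested by an exact permutation of the 6 arrays. This permutation did not keep to the slides.

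The test was checked on simulated data for this comparison, with the levels, spreads and slide deviations of 28853 real probes and 200 changed probes. The fit without a block called none of 67 probes changed 1.5-fold, 28.4% of those changed 2-fold and 69.7% of those changed 4-fold, with 0 unchanged probes called. With the replicate number as a block the shares were 52.2%, 95.5% and 97.0%, with 16 unchanged probes among 179 called. Only 200 probes were changed there, against 12276 called in the real data, so the adjustment for multiple testing was stricter. These shares therefore do not carry over to the real comparison. The simulated slide deviations were shared by both arrays of a slide, which favours the block by construction.

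The replicate numbers in the labels and the slides in the file headers coincided, each slide holding the control and the aluminium array of 1 number. Whether the numbers pair the arrays was checked before the blocked fit was made. The deviations from the group means correlated by 0.615, 0.798 and 0.711 between same-numbered arrays across probes, and between -0.653 and -0.042 between arrays of different numbers. Deviations cancel within a group, so positive same-number values by themselves push the others towards negative ones, which add no separate evidence. All 3 same-number values were over 0.1, so the numbers were taken to pair the arrays. Slides 1 and 2 were scanned on one day and slide 3 on another.

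The comparison, its test, the filter, the alternatives and the rule for naming genes were chosen before the data were examined. The alternatives were normexp background correction with an offset of 50, quantile and median scaling, the deposited value table, no filter and a stricter filter on dim probes, keeping outlier spots, a trended robust variance, the replicate block, 1 probe per identifier, and leaving out each array in turn. The normexp alternative was planned on spot means, which the data lack, so the spot medians were used in their place. Spike-in scaling and leaving out slide 3 were added after the data had been seen.

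The rule for naming was to give the 8 highest and the 8 lowest called probes whose description names a protein, and the leading members of 41 gene lists fixed as patterns on descriptions. The files give a probe a sequence identifier or, for 894 probes, only its own name, and no gene name or description. Of the probes, 0 had an identifier matching any of the 79372 genes of the RefSeq table for the assembly ASM71507v2 of the tobacco cultivar K326. No gene was therefore named, the gene lists and their set tests were not run, and 4 probes are given by their identifiers. They are the 2 highest and 2 lowest called probes, 1 per identifier, that were well above background on all 6 arrays and whose groups did not overlap. No genome coordinates were used here.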

Results

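Transcript levels were measured in suspension-cultured cells of the wild-type tobacco (Nicotiana tabacum) line SL that had been incubated for 18 h with or without 100 µM aluminium chloride. Aluminium is a metal whose soluble ion is toxic to plant cells in acid media, and the treatment medium was held at pH 5.0. There were 3 control samples and 3 aluminium-treated samples, each hybridised to its own single-colour array. The labels describe the samples as different replicates without naming separate cultures, so the p-values measure the spread between these samples, which may be partly technical.

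The array carried 43759 different tobacco probes, of which 42865 were tied to 39531 sequence identifiers and 894 were listed under their own probe name only. Between 62.1% and 74.7% of the probes were well above background on an array. The arrays of replicates 1 and 2 had 75th-percentile signals between 2789 and 3224. Those of replicate 3, hybridised on a slide that was scanned on another day, had 1405 in the control and 1180 with aluminium. No tobacco spot was saturated on any array. The 11 probes printed in 5 spots differed between their spots by a median SD of 0.066 to 0.11 on the log2 scale, depending on the array. The number of arrays, 3 per group, limits the precision.

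The comparison asked which transcripts differed between cells cultured with and without aluminium. Aluminium treatment was accompanied by a change in a large part of the measured transcripts, in both directions. Of 28861 probes tested, 12276 (42.5%) differed at an adjusted p under 0.05, 6456 of them higher and 5820 lower in aluminium-treated cells. A difference of at least 2-fold was reached by 4721 of these probes, 2513 higher and 2208 lower. The transcripts that changed could not be assigned to genes or pathways, because the files pair the probes with sequence identifiers or their own probe names only, and none of these matched the RefSeq gene table used for names. The adjusted p-values are from limma with Benjamini-Hochberg adjustment, two-sided. With the replicate number, which is also the slide, as a block, the same test called 18765 probes, 10059 higher and 8706 lower, and 4961 of at least 2-fold. Without the 2 arrays of replicate 3 the unblocked count was 8063, with 4298 of at least 2-fold. Scaling the arrays by their spike-in controls instead of their 75th percentile left 1363 calls in the fit without a block. The median standard error was then 0.66 against 0.15. The median size of the 4721 differences, higher and lower together, was 1.52 against 1.51 (log2). No count with both spike-in scaling and the block is given here. How much of the loss came from leaving out the pairing therefore cannot be told. The balance of higher and lower calls depended on the scaling, on replicate 3 and on the filter. Over all arrays it was 5715 to 6169 after quantile normalization and 636 to 727 by the spike-ins. Without replicate 3 it was 4077 to 3986 by the 75th percentile and 4892 to 2776 by the spike-ins. Among changes of at least 2-fold, the 75th percentile gave 2133 to 2165 without replicate 3. It gave 2055 to 1991 when only probes well above background on all 6 arrays were tested.

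Large changes were found on both sides. At the same threshold, 723 probes rose and 606 fell at least 4-fold, 265 rose and 212 fell at least 8-fold, and 84 rose and 61 fell at least 16-fold. Of the 4721 probes changed at least 2-fold, 4032 were well above background on all 6 arrays. In the others the dim group can lie near the floor, so the size of their folds is uncertain. With normexp background correction 3330 probes were called at 2-fold or more. The counts at 4-fold and above are not given for that correction or for the stricter filter. Over the probes called, the median size of the log2 difference was 0.82, while the median standard error over all tested probes was 0.15. Over all tested probes the log2 difference had a median of 0.07 and quartiles of -0.35 and 0.45. In 15744 probes (54.6%) the 3 aluminium values lay entirely above or entirely below the 3 control values, against the 10% that chance gives for 6 exchangeable arrays. The arrays are paired by slide, and the 3 other splits that keep the arrays of every slide apart gave 0.65% to 0.97%. Those splits mix treated and control arrays on each side, so a large difference between the groups itself lowers these values. They are therefore not a chance level.

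**Figure D1:**
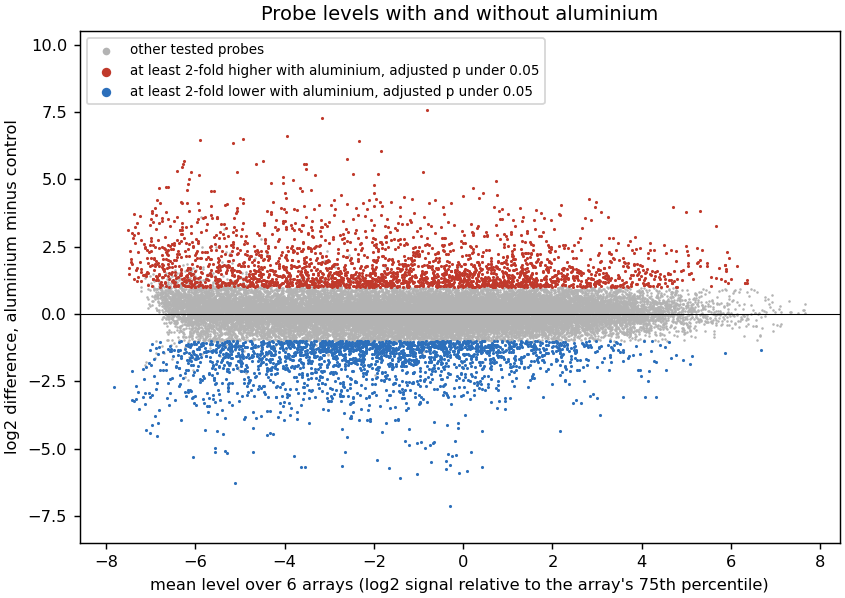
Log2 difference between aluminium and control (vertical axis) against the mean level over the 6 arrays (horizontal axis, log2 signal relative to each array's 75th percentile) for the 28861 tested probes. The 2513 probes that rose at least 2-fold are red, the 2208 that fell at least 2-fold are blue, and both kinds occur from the dimmest to bright probes.

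The 2 probes that rose most among those well above background on all 6 arrays were A_95_P121867 and A_95_P163777, and the 2 that fell most were A_95_P188152 and A_95_P090213. They were chosen for their size after the values were seen, and the genes behind them are not named in the files. Probe A_95_P121867 (identifier DW001957) went from a log2 level of -4.59 ± 0.099 in control cells to 2.98 ± 0.18 with aluminium (SD, n = 3), relative to each array's 75th percentile. This is a log2 difference of 7.57 ± 0.13 (SE), or 190-fold, with a limma adjusted p of 1.97e-05. Probe A_95_P163777 (EH622852) rose 84.9-fold, from -5.55 ± 0.41 to 0.86 ± 0.44 (SD, n = 3; limma adjusted p = 5.22e-05). Its log2 differences on the 3 slides were 6.31, 5.61 and 7.30, the widest spread of the 4 probes. Probe A_95_P188152 (TA14506_4097) was among the brighter probes in control cells at 3.27 ± 0.16 and was at -3.86 ± 0.40 with aluminium (SD, n = 3), a log2 difference of -7.13 ± 0.22 (SE; limma adjusted p = 2.66e-05). Probe A_95_P090213 (BP530860) fell from 1.63 ± 0.094 to -4.45 ± 0.16 (SD, n = 3), a log2 difference of -6.08 ± 0.12 (SE; limma adjusted p = 1.97e-05). With normexp background correction of the spot medians and an offset of 50, the log2 differences were smaller, at 6.80 (111-fold) for A_95_P121867, 4.99 (31.9-fold) for A_95_P163777, -6.61 for A_95_P188152 and -5.30 for A_95_P090213.

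**Figure D2:**
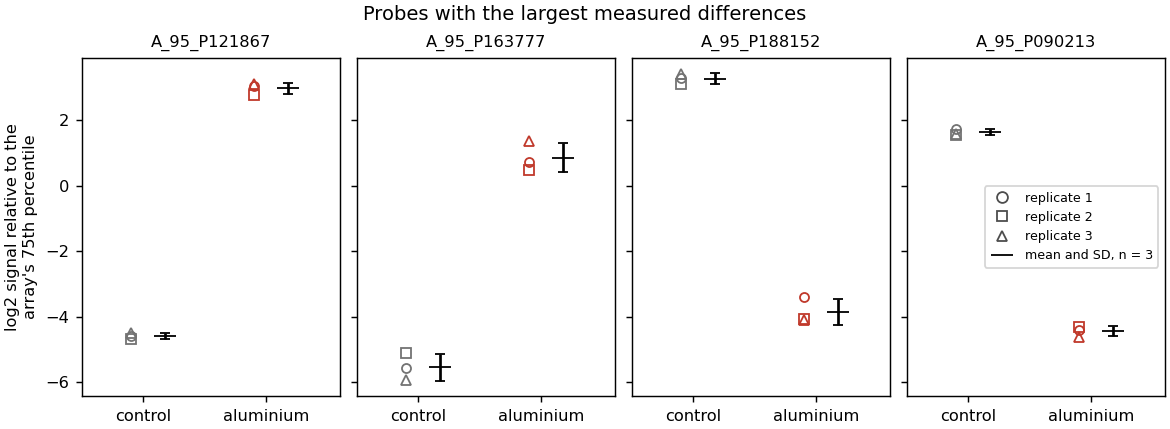
Log2 signal relative to the array's 75th percentile (vertical axis) on each control and aluminium array for 4 probes; symbols mark replicates 1 to 3, and the bars give the mean and SD of 3 arrays. The aluminium arrays of A_95_P121867 and A_95_P163777 lie above all their control arrays, and those of A_95_P188152 and A_95_P090213 lie below.

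Each of the 3 slides held the control and the aluminium array of 1 replicate number, so the response could be followed in 3 separate pairs of arrays that share no control. The log2 differences of the tested probes correlated between slides with Pearson's r of 0.943 for slides 1 and 2, 0.928 for slides 1 and 3 and 0.909 for slides 2 and 3. These are correlations across probes, which are not independent replicates. Over all tested probes with a value on every slide, called or not, 81.2% changed in the same direction on all 3, where independent signs would give 25%. The probes called at least 2-fold higher had median log2 differences of 1.48, 1.40 and 1.70 on slides 1, 2 and 3, and those called at least 2-fold lower had -1.54, -1.47 and -1.55. These probes were selected on the mean of the same 3 slides, so medians beyond 2-fold on each slide were largely set by that selection. Slide 3 had more probes at least 2-fold higher than the others, 3722 against 2669 and 2324, while the numbers at least 2-fold lower were 2420, 2404 and 2330 on slides 3, 1 and 2. On every slide the control array was in position 1 and the aluminium array in position 2, so array position and treatment cannot be told apart.

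**Figure D3:**
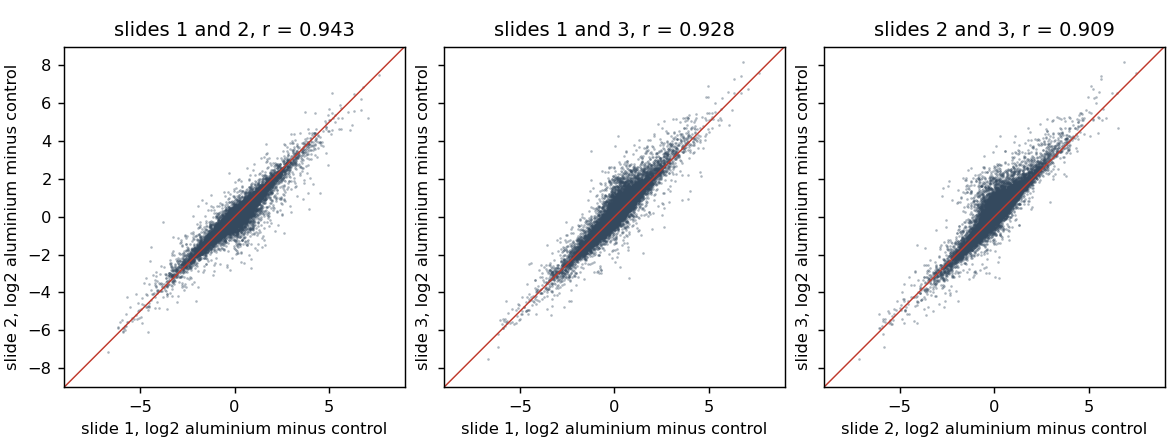
Log2 difference between the aluminium and the control array of one slide plotted against that of another, for the 28853 to 28859 tested probes with a value on both, with the line of equality in red. The points follow the line on all 3 pairs of slides (r = 0.943, 0.928 and 0.909).

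Several transcripts were represented by more than 1 probe, which gave a second measurement of the same change. Among 2313 identifiers with at least 2 tested probes, the log2 differences of the first 2 probes correlated with r = 0.919. At least 1 probe was called with a 2-fold change for 482 of these identifiers. In 469 of the 482, all tested probes of the identifier changed in the same direction, and no identifier had probes called in opposite directions at 2-fold. Tobacco is an allotetraploid, so the signal of a probe can include near-identical transcripts from both parental genomes.

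Higher and lower calls were not spread alike over the range of probe brightness, which also depends on the probe and so does not rank transcripts by abundance. In the brightest quartile of probes 2027 were higher and 1272 lower (61.4% higher), and among changes of at least 2-fold 579 were higher and 264 lower. In the second quartile from the dim end the balance was the other way, with 1489 higher and 1756 lower. The dimmest quartile had 1297 higher and 1101 lower, and the third had 1643 higher and 1691 lower. The median standard error of the log2 difference fell from 0.24 in the dimmest quartile to 0.12 in the brightest. Under quantile normalization, which gives all arrays the same distribution, the brightest quartile had 1581 higher and 1718 lower calls, so the excess of higher calls among all calls there depended on the scaling. By the spike-ins it was 106 to 63 over all arrays and 1634 to 442 without replicate 3, where the 75th percentile gave 1340 to 747. Among its changes of at least 2-fold, quantile normalization left 466 higher and 338 lower.

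The 1000 brightest probes of an array took 43.1% ± 0.19 of its summed signal in control cells and 44.9% ± 0.37 with aluminium (SD, n = 3). The share was higher with aluminium on all 3 slides, at 44.9% against 43.2%, 44.6% against 42.9% and 45.4% against 43.2%. A two-sided exact permutation test gave p = 0.1, the smallest p that 3 unpaired samples against 3 allow. It ignored the pairing by slide, and exchange within slides only would not allow a p this small.

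Some transcripts were detected in one condition only. While 26525 probes were well above background on all 6 arrays, 178 were so on all aluminium arrays and on no control array, and 67 on all control arrays and on no aluminium array. For such probes the dim group gives only an approximate bound, taken against the higher of the probe's own signal and the lowest signal that was well above background on that array. Where the probe's own signal was the higher, the measured dim signal was used, so the bound is not a strict limit. By this bound 105 of the 178 were at least 2-fold higher with aluminium and 43 at least 4-fold higher, with a highest bound of 35.9-fold. Of the 67, 54 were by this bound at least 2-fold lower with aluminium and 26 at least 4-fold lower, with a highest bound of 34.1-fold. The limma test called 167 of the 178 and 63 of the 67 in the matching direction. The 67 had to be well above background on the control array of replicate 3, which had the fewest such probes. It had 27163, against 29658 on the aluminium array of the same slide, so the 178 and the 67 are not directly comparable. Of the 10 splits of the 6 arrays into 3 and 3, 3 gave as many probes detected on one side only as the 245 of the real one, itself included, and the highest other gave 318 with both arrays of slide 3 on one side. The real split keeps the 2 arrays of every slide apart, and the 3 other splits that do so gave 11 to 27. Those 3 mix treated and control arrays on each side, so a large difference between the groups itself lowers their counts. They are therefore not a chance level, and 4 such splits, the real one included, cannot give a share under 0.05.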

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

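Of the results below, spike-in scaling and leaving out slide 3 were tried only after the data had been seen. The main count of 12276 changed probes, and that of 4721 changed at least 2-fold, stayed within 1.5 times under normexp correction, quantile normalization, median scaling, the deposited value table, both filters on dim probes, kept outlier spots, the trended robust variance and 1 probe per identifier, at 8898 to 12716 and 3330 to 4818. Leaving out 1 array at a time gave 9280 to 10470 changed probes and 4455 to 4866 of at least 2-fold. With the replicate block, 18765 probes were called, 12260 of them also called without it, and 4961 of at least 2-fold; the block ended the call of none of the 4 probes given by identifier. Leaving out slide 3 gave 8063, and 16318 with the replicate block. Scaling by the spike-ins, without the block, gave 1363, all of them of at least 2-fold, and 7668 when slide 3 was also left out. The median standard error rose to 0.66 under spike-in scaling. The tobacco probes moved against the spike-ins by -0.71 on slide 3 and by 0.03 and 0.18 on slides 1 and 2. Spike-in scaling moved the median log2 difference of the tested probes from 0.07 to -0.08. This downward shift made higher differences smaller and lower ones larger. Higher calls fell from 6456 to 636 and lower calls from 5820 to 727. The loss of lower calls therefore came with a wider spread between arrays and not with smaller differences. For higher calls both the spread and the shift count. With slide 3 left out, 63.8% of the calls were higher under spike-in scaling (4892 against 2776) and 50.6% under percentile scaling (4077 against 3986). No probe called both in the main test and under an alternative changed sign. As the alternatives reuse the same arrays, a change of sign in such a probe was hardly possible. The 4 probes given by identifier were chosen for their size in the same arrays, so what they show says little about the other calls. They kept their direction and their call in all 80 alternative values, with adjusted p of at most 0.0049 (limma). Their log2 differences ranged from 6.80 to 7.69 for A_95_P121867, 4.99 to 6.62 for A_95_P163777, -7.36 to -6.61 for A_95_P188152 and -6.23 to -5.30 for A_95_P090213, the smallest sizes all under normexp correction. The lowest same-number correlation of deviations, 0.615, moved to 0.762 under normexp correction and to 0.432 without a filter on dim probes. The planned gene list tests were not run, as the probes have no gene names here. The real split of the 6 arrays called 12276 probes and the highest of the other 9 called 0, so 1 of 10 splits gave as many; 10 splits are too few for a share under 0.05. The 3 other splits that part all 3 pairs, as the real one does, called 0 with the block as well. Every split but the real one mixes treated and control arrays, so a large difference between the groups itself keeps those counts low. Array 3 of each group limits the dim probes: 62.1% of probes were well above background on the control and 67.8% on the aluminium array.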

Other observations

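Except for the same-number correlations after quantile normalization, the tests in this part were chosen after the main comparison had been seen. Those correlations were chosen before the data were examined. The agreement between probes of one identifier was itself seen before its test was written down.

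The only grouping of transcripts that the array files offer is the series of their sequence identifiers, and these series responded unequally. Of 1583 tested probes whose identifier is EH followed by a number, 263 (16.6%) rose at least 2-fold with aluminium, against 8.25% of all other tested probes (odds ratio 2.22, Fisher's exact test, Benjamini-Hochberg adjusted p = 1.17e-23 over 42 comparisons of 21 series, probe names counted as a series, in 2 directions, of which 13 passed). The same series did not stand apart among probes that fell, with 7.96% against 7.63% (odds ratio 1.05, Fisher's exact test, adjusted p = 0.693). A higher share of risers was not particular to this series: 15.6% of 141 AY probes (adjusted p = 0.0212) and 14.2% of 289 AB probes (adjusted p = 0.00753) rose at least 2-fold by Fisher's exact test, and both series also had more probes that fell, with 15.6% and 13.5%. A higher share of probes that fell was also found in the series DQ (19.1%), X (16.2%), AF (15.1%) and TA (9.11%), and a lower share of risers in DV (6.20%) and TA (7.42%). The numbers of the EH series fell into separate runs, which were compared after this was seen. In the run whose numbers begin with 613 to 624, 255 of 1452 probes (17.6%) rose at least 2-fold, and in the run beginning with 663 to 666, 8 of 131 (6.11%), which differed by Fisher's exact test (odds ratio 0.305, p = 0.000325). Probes with identifiers beginning with FG fell at least 2-fold less often, 5.85% against 7.90% of the rest (adjusted p = 0.000104), and so did those beginning with BP, 5.16% against 8.20% of the rest (odds ratio 0.61, Fisher's exact test, adjusted p = 1.9e-13). Probes are not independent replicates, so these p-values describe this array and not a population of cultures.

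The excess in the EH series was present on each slide, with 16.7%, 15.1% and 22.1% of its probes at least 2-fold higher on slides 1, 2 and 3 against 8.82%, 7.64% and 12.4% of the rest. The series was picked for its calls on these same 3 slides, which the other settings reuse. Neither the slides nor the settings are therefore separate support for the excess. The odds ratio was 2.24 under quantile normalization, 2.22 with the replicate block, 2.27 with 1 probe per identifier and 3.11 under spike-in scaling, where fewer probes passed, 94 of the series (5.94%) against 1.99% of the rest. The brightness of the probes does not account for the excess: within quartiles of mean level the common odds ratio was 2.2, with a 95% interval of 1.92 to 2.53, where brightness as the whole cause needed a value near 1. No biological explanation was tested.

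Arrays with the same replicate number deviated together from their group means. A trend with brightness between slides would have vanished under quantile normalization, but the lowest of the 3 same-number correlations was 0.607 after it. If the shared deviation lay in the spots of a slide, 2 probes of one transcript should not have shared it, and if it lay in the RNA they should have. Their slide deviations correlated by 0.404, 0.24 and 0.264 on slides 1, 2 and 3 over 2312 identifiers, against 0.02 to 0.027 between probes that are neighbours in brightness, and the lowest value lies between the bounds set for either answer. Cultures or RNA preparations handled together, and the labelling and scanning of a slide, therefore stay open and cannot be told apart here for the shared deviation.

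For the difference between treated and control arrays, position or quality of single spots is argued against by the correlation of 0.919 between the log2 differences of 2 probes of one identifier, which sit at different spots. The position of the whole array on the slide stays confounded with the treatment.

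The 8 spike-in control probes that were well above background on all arrays did not follow the tobacco probes alike on the 3 slides. From control to aluminium, the 75th percentile of the tobacco probes relative to the spike-ins changed by 0.03 ± 0.054 on slide 1, 0.18 ± 0.12 on slide 2 and -0.71 ± 0.24 on slide 3 (log2, median ± SD over spike-in probes).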
